A study of Homo sapiens with 12 samples.

How the data were processed

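Gene expression was measured in 12 tissues of a reconstructed human epidermis model (Epi-200), 3 per group, after 0 or 0.5 Gy of alpha particles and a harvest at 1 h or 16 h. Per the labels, the design was 3 independent experiments with 1 tissue for each data point. The sample descriptions name protons and another harvest time, while titles, treatment protocol and sample characteristics name alpha particles and 1 h or 16 h, which were used. Per the labels, RNA was purified on columns, checked for amount and integrity, and labelled with Cy3 from 0.2 µg by a low-input linear amplification kit.

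The deposited intensity values were made by Agilent Feature Extraction 9.1.3.1, per the file headers: background was subtracted with a spatial detrend and the signal was corrected for a multiplicative trend within each array. The deposited values were not scaled between arrays and not on a log2 scale, per the file headers and the values themselves. The deposited value table equalled this processed signal for every spot. No genome build is given in the sources used here. Each array had 45015 spots in 532 rows and 85 columns, with 41000 probes that were not controls. XIST and Y-linked genes were left out, which gave 40926.

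Processed signals were scaled so that the 75th percentile of each array was 624.3, set to at least 10 and taken to log2. Values with an outlier flag, 1.44% of the values in the matrix, were left out. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which held for 29815 probes, and the brightest kept probe stood for a gene, since 5607 genes had several. Gene names came from the probe's accession (25398 probes), symbol (2510) or synonym (789) in the RefSeq gene table of assembly GRCh38.p14, used for names alone, or from the array file (1659), and 10644 probes had none. Of 22276 genes or unnamed probes, 22037 could be tested, 15862 of them named, and 239 had too few values left.

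The test was limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, moderated variances and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The contrasts were irradiated against unirradiated at 1 h and at 16 h, their average, their difference, and 16 h against 1 h in unirradiated tissues. The p-values measure the spread between tissues and arrays within groups. In groups whose arrays all lay on 1 slide, that spread leaves out differences between slides. Gene lists, 28 in all, were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with the rotation test fry. Files were read with version 1.17.8 of the R package data.table, and tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The contrasts, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except those said to be chosen after seeing the data. For both irradiation contrasts and for time the rule took, in each direction, the 10 genes with the largest change among those past the threshold whose groups did not overlap, filled up by lowest p, and 5 per direction for the average and the difference. It further took up to 4 members of each described list by lowest p, and a fixed panel of 14 radiation response genes reported whatever their result. The text names some of the genes that this rule gives.

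The steps were tested on simulated data with known changes in 22039 genes. At 1.5-fold, 2-fold and 4-fold, 8.3, 33.8 and 75% of the changed genes were recovered for irradiation at 1 h, and 1.7, 35 and 66.7% at 16 h. For the average the shares were 20, 62.5 and 91.7%, for the difference 3.3, 15 and 56.7%, and for time 3.3, 25 and 73.3%, with 3 to 8 false calls per contrast. A shift of 0.3 given to the 37 p53 targets was recovered with 0 other lists called. The simulated values varied independently between genes and arrays, without slide effects or correlation within lists. In the real data the estimated correlation was 0.181 for p53 targets, 0.478 for mitosis and 0.629 for DNA replication. The simulation therefore does not measure false calls of genes or lists on the real arrays.

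Alternatives were other scalings (median centring, quantile, the value table as given), normexp background correction, other filters on dim probes, the mean of a gene's probes or single probes, and slide as a fixed or random block. Further ones were the replicate number as a block, the arrays of the contrast alone, variance trend, array weights, other thresholds, other set tests and each array left out in turn. Chosen after seeing the data were keeping spots with an outlier flag, leaving out genes with any, leaving out the first 12 columns of spots, and local spatial centring in windows of 31 rows by 5 columns. The areas of rows and columns of spots in which calls are counted were also chosen after seeing the data.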

Results

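Expression was measured in a reconstructed human epidermis model (Epi-200), a layered keratinocyte tissue grown in culture, after irradiation with alpha particles, a form of densely ionising radiation. Tissues received 0 or 0.5 Gy and were harvested 1 h or 16 h later. The 4 groups had 3 arrays each, 12 in all, with RNA of 1 tissue per array and 1 colour (Cy3). The question was which genes respond to a low alpha-particle dose at an early and a later time. Between 71.2 and 74.9% of spots were well above background, and the 75th percentile of processed signal ran from 509.6 to 747.4. The software's own spike-in fit had a slope of 0 on irradiated 1 h replicate 1 and of 1.006 to 1.031 on the other arrays. The number of arrays limits the precision.

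The 12 arrays lay on 3 slides that cut across the groups. Slide 1 held the 3 unirradiated 1 h arrays and irradiated 1 h replicate 1. Slide 2 held irradiated 1 h replicates 2 and 3 with unirradiated 16 h replicates 1 and 2, and slide 3 held unirradiated 16 h replicate 3 with the 3 irradiated 16 h arrays. The first principal component took 39.7% of the variance. On it the 4 arrays of slide 1 lay between -87.4 and -33.7, and the 8 arrays of slides 2 and 3 between 16.8 and 37.3. The irradiated array of slide 1 was at -51.5 on this component. The median correlation between arrays of different groups was 0.9818 on the same slide and 0.967 on different slides. Within a group it was 0.9854 on the same slide and 0.9786 on different slides.

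At 16 h the 37 measured p53 target genes, which are switched on by p53, a transcription factor of the DNA damage response, were higher as a set in irradiated tissues in a test with a preset correlation, with a median log2 change of 0.24 and 32 of 37 members above 0. The call ended at adjusted p = 0.279 with an estimated correlation, and in the rotation test fry at 0.409. The strongest members were GDF15, a secreted stress cytokine, at 1.40 (SE 0.53), CDKN1A, the p21 inhibitor of the cell cycle, at 0.86 (SE 0.34), TIGAR, a regulator of glycolysis, at 0.65 (SE 0.27) and RPS27L at 0.70 (SE 0.34). The DNA replication list, of the enzymes and loading factors that copy DNA, was lower (adjusted p = 0.473 with an estimated correlation), with a median of -0.56 and 30 of 31 members below 0, among them RRM2 at -0.91 (SE 0.34), MCM7 at -0.56 (SE 0.25), RFC4 at -1.04 (SE 0.48) and CDT1 at -1.05 (SE 0.49). The mitosis list was lower as well (adjusted p = 0.473 with an estimated correlation), with a median of -0.55 and 26 of 27 members below 0, among them the microtubule depolymerase KIF2C at -0.56 (SE 0.22) and the topoisomerase TOP2A at -0.97 (SE 0.44). RPS27L was at 0.40 without unirradiated 16 h replicate 1, CDT1 at -1.58 without unirradiated 16 h replicate 3, and RFC4 and TOP2A at -0.63 each without irradiated 16 h replicate 3. None of these members passed the threshold by itself, with 3 arrays per group and an adjusted p of 1 in the limma test over all genes, and 0 members of the 3 lists passed it adjusted over the list alone. At unadjusted p under 0.05, 3 of the p53 targets, 2 of the replication genes and 3 of the mitosis genes were counted.

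The set test, limma's camera with a preset correlation of 0.01 between genes, gave adjusted p = 1.64e-08 for the p53 targets, 6.5e-08 for DNA replication and 2.01e-07 for mitosis. With an estimated correlation none of these calls held (adjusted p = 0.279 with an estimated correlation for p53 and 0.473 for the others), and fry gave 0.463 for replication and 0.409 for mitosis. The values within slide 3, the 1 slide holding both 16 h groups, were far smaller. The mean of the p53 targets differed there by 0.024 against 0.286 over all 16 h arrays, that of replication by -0.081 against -0.643, and that of mitosis by -0.189 against -0.555. Fitting slide as a fixed block gave median changes of 0.031, -0.095 and -0.26 and ended all 3 calls. That fit is no separate check, since at 16 h it compared the groups on slide 3 alone, with 1 unirradiated array. Under the normexp background correction, which moved the median of all genes from -0.038 to 0.138, the p53 list stood at 0.20 and no longer passed, while replication at -0.37 and mitosis at -0.11 did. Unirradiated 16 h replicate 3 had a p53 score of 0.208 and a replication score of 0.035, where replicates 1 and 2 had -0.162 and -0.209 for p53 and 0.877 and 0.88 for replication. Without that array the medians were 0.34 for p53, -0.77 for replication and -0.78 for mitosis. Leaving out irradiated 16 h replicate 1 brought the p53 median to 0.15, leaving out unirradiated 16 h replicate 2 brought it to 0.16, and leaving out irradiated 16 h replicate 3 brought the mitosis median to -0.34. The 3 lists stayed past the preset-correlation threshold in each of the 12 fits without 1 array.

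**Figure D1:**
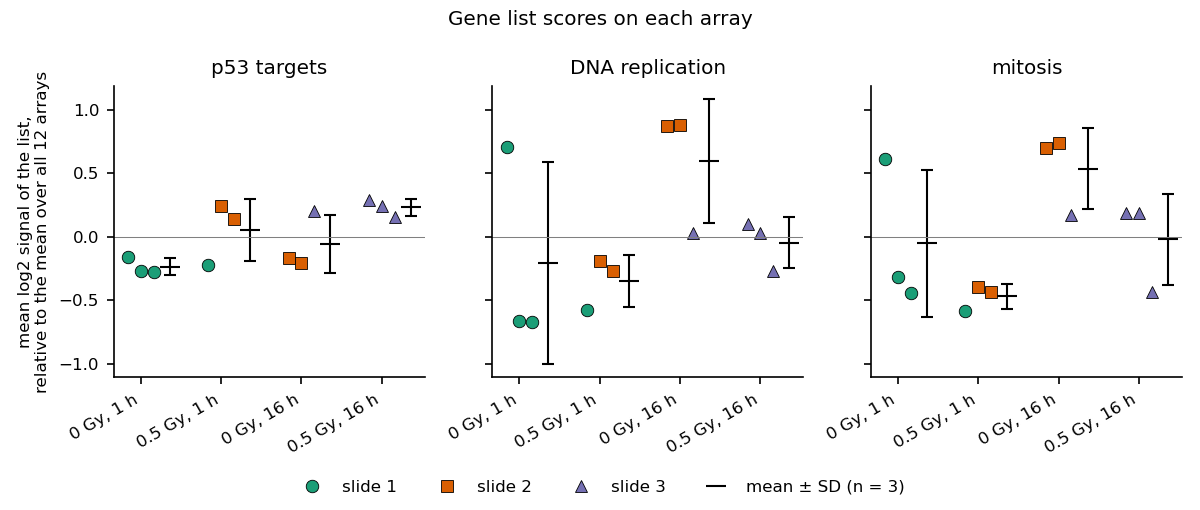
Each point is 1 array, with the mean log2 signal of a gene list on the y axis, relative to its mean over the 12 arrays, and the 4 groups on the x axis; bars are means ± SD (n = 3). Unirradiated 16 h replicates 1 and 2 on slide 2 had replication scores of 0.877 and 0.88, and unirradiated 16 h replicate 3 on slide 3 lay at 0.035, beside the irradiated arrays of its slide.

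A further 8 lists passed the preset-correlation test at 16 h, and none of them passed with an estimated correlation. The 32 replication-dependent histone genes had a median of 0.11, with H4C8 at 0.38 (SE 0.20) and H1-3 at 0.61 (SE 0.43), at adjusted p = 2.17e-04 and adjusted p = 0.152 with an estimated correlation. The 44 cytosolic ribosomal protein genes had a median of 0.059, with adjusted p = 8.01e-03 and adjusted p = 0.473 with an estimated correlation. RPS19 was at 0.16 (SE 0.14), where its other probe gave -0.026, and RPL4 at -0.17 (SE 0.18). Immediate early genes had a median of 0.044, with the AP-1 subunit FOSL1 at 0.67 (SE 0.28). Early differentiation genes had 0.095, with the cadherin DSC2 at 0.73 (SE 0.40) and the differentiation factor ZNF750 at 0.78 (SE 0.47). Heat shock proteins had 0.075, with HSPA6 at 0.25 (SE 0.17) and DNAJA1 at 0.29 (SE 0.22). Lower were double-strand break repair genes at -0.24, with FANCA at -1.18 (SE 0.53), EXO1 at -1.32 (SE 0.59) and MRE11 at -0.46 (SE 0.20), interferon-stimulated genes at -0.26, with STAT2 at -0.93 (SE 0.21) and OAS2 at -1.26 (SE 0.53), and metallothioneins at -0.35, with MT1G at -0.43 (SE 0.26) and MT2A at -0.54 (SE 0.33). These 6 lists each had an adjusted p of 0.0142, and with an estimated correlation adjusted p was 0.411 for immediate early genes and heat shock proteins, 0.19 for early differentiation and 0.473 for the other 3. Without unirradiated 16 h replicate 1, DSC2 was at 0.24, ZNF750 at 0.37, H1-3 at 0.26, H4C8 at 0.22 and MT2A at 0.092, and without unirradiated 16 h replicate 3 DSC2 was at 1.13, H4C8 at 0.60 and MT2A at -1.18. HSPA6 was at 0.13 without irradiated 16 h replicate 3 and DNAJA1 at 0.14 without irradiated 16 h replicate 1. Among all members, 1 interferon-stimulated gene was lower adjusted over the list alone and 0 passed over all genes.

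Relative to the median of all genes, 5 of these lists turned their direction under normexp: the ribosomal list stood at -0.15, heat shock at -0.090, early differentiation at -0.065, immediate early genes at -0.060 and histones at 0.010. Under it the repair list stood at -0.012 and the interferon list at 0.059, both lower relative to all genes but no longer past the threshold. In the fit with slide as a fixed block the repair list was at -0.051 and the metallothioneins at 0.038, each opposite to its first direction relative to the other genes. At 16 h that fit rested on 1 unirradiated array, that of slide 3. That fit kept the calls of the ribosomal list, at 0.21, and of heat shock, at 0.18, and ended those of histones (0.090), immediate early genes (-0.017), early differentiation (0.058) and interferon-stimulated genes (-0.050). It called endothelial markers lower, at -0.35 (adjusted p = 0.0116), which did not pass as reported (-0.13, adjusted p = 0.224, and adjusted p = 0.473 with an estimated correlation). The repair call ended without unirradiated 16 h replicate 1 (-0.14), replicate 2 (-0.25) or irradiated 16 h replicate 3 (-0.13), and the interferon call without unirradiated replicate 1 (-0.12) or irradiated replicate 2 (-0.20). The metallothionein call ended without unirradiated 16 h replicates 1 (-0.20) or 2 (-0.26) or irradiated 16 h replicates 1 (-0.34) or 2 (-0.30). The call for immediate early genes ended without unirradiated replicate 2 (0.015) or irradiated replicates 1 (-0.006) or 2 (-0.003), and that for early differentiation without unirradiated replicate 2 (0.060) or irradiated replicate 2 (0.067). The heat shock and ribosomal calls ended without unirradiated 16 h replicate 3 (0.019 and -0.026) or irradiated 16 h replicate 3 (0.048 and 0.034). Values of calls that held moved most without unirradiated 16 h replicate 1 (ribosomal 0.11, heat shock 0.12), unirradiated 16 h replicate 3 (immediate early genes 0.10, metallothioneins -0.54) and irradiated 16 h replicate 3 (immediate early genes 0.16). The histone call held without each array, and the count of lists was 7 rather than 11 without unirradiated 16 h replicate 2 or irradiated 16 h replicate 2.

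At the level of single genes, 8 of 22037 genes passed the threshold at 16 h, 0 higher and 8 lower. Of these, 4 carry a gene name. KRTAP4-11, a hair keratin-associated protein, fell by 1.73 on the log2 scale (SE 0.19, adjusted p = 0.0107), and CPN1, a carboxypeptidase subunit, fell by 1.79 (SE 0.22, adjusted p = 0.0171). ENPP4, a membrane phosphodiesterase, fell by 2.02 (SE 0.26, adjusted p = 0.0232). LOC401176 was not well above background on any irradiated 16 h array and was an estimated 5.53-fold lower than in unirradiated tissue (adjusted p = 0.0107). The cytokine IL15 at -2.15 (SE 0.33), OPRL1 at -1.74 (SE 0.26), TLE6 at -1.37 (SE 0.20) and GSTA3 at -1.15 (SE 0.19) did not pass, with adjusted p from 0.0599 to 0.127. On the upward side, the motor linker MYRIP was at 1.18 (SE 0.45, adjusted p = 1). Counts at an unadjusted p under 0.05 were 905, of which 39 were higher, where 1102 would be expected by chance.

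All 8 called probes lay in the first 12 of 85 columns of spots, which held 13.3% of the tested genes, as did 59 of the 72 probes with an unadjusted p under 0.001. Leaving those columns out, an alternative chosen after seeing the data, left 0 calls by construction, and normexp gave 0. After local spatial centring, also chosen after seeing the data, all 8 stayed called among 79 genes, 37 of them in these columns. Within slide 3 the changes were -1.45 for KRTAP4-11, -1.50 for CPN1 and -1.85 for ENPP4. The fit with slide as a fixed block gave these values too, and its count was 0. The count was 1 without a filter on dim probes, 52 from the arrays of the contrast alone and 634 with array weights. With the replicate number as a block it was 0. The count was 15 without unirradiated 1 h replicate 1 and 32 without irradiated 1 h replicate 2. It was 1 without unirradiated 16 h replicates 1 or 2 or irradiated 16 h replicate 2, 5 without unirradiated 16 h replicate 3, and 0 without irradiated 16 h replicates 1 or 3. The calls of KRTAP4-11, CPN1 and LOC401176 were lost in 5 of the 12 fits without 1 array, those without unirradiated 16 h replicates 1 or 2 or any irradiated 16 h array, and that of ENPP4 in 7, with values from -2.18 to -1.85.

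**Figure D2:**
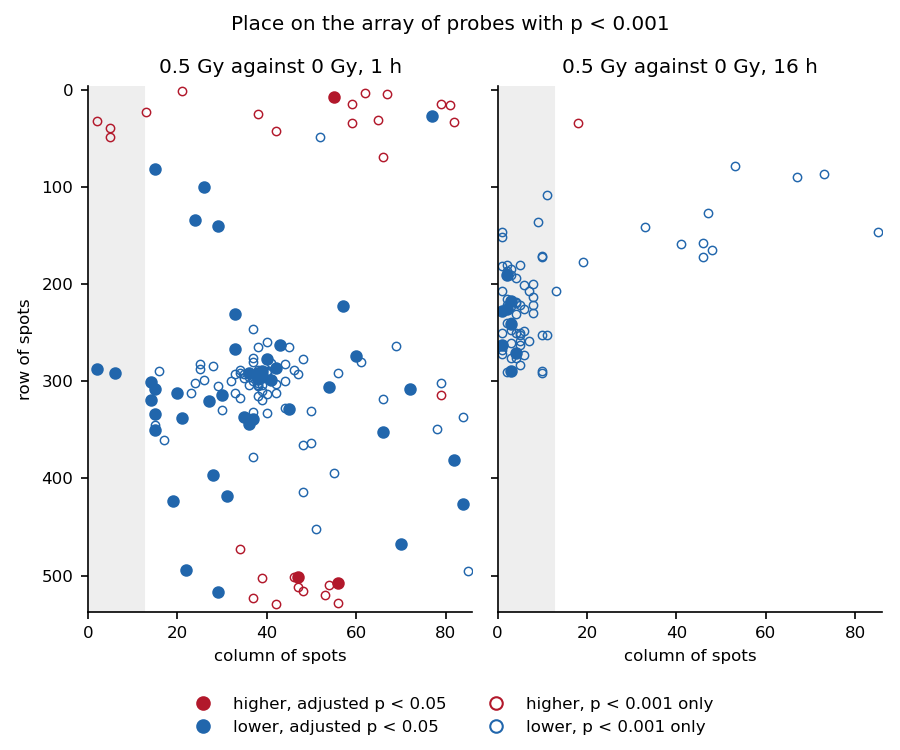
Each point is a probe with an unadjusted p under 0.001, at its row and column of spots on the array, for irradiation at 1 h (left) and 16 h (right); filled points passed the adjusted threshold, red is higher and blue lower after 0.5 Gy, and the grey band marks the first 12 columns. At 16 h 59 of 72 probes lay in the band; at 1 h 29 of the 30 higher probes lay in the 80 outer rows at the top or at the bottom, which held 29.2% of tested genes, as did 6 of the 116 lower ones, and 68 of those 116 lay in rows 260 to 330 and columns 11 to 50, which held 6.4% of tested genes; these areas were chosen after seeing the data.

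The radiation response panel was reported whatever its result, and 0 of its 13 measured genes passed the threshold at 16 h. GDF15 and CDKN1A are given above, with 12.44 ± 0.29 against 11.04 ± 1.19 log2 units for GDF15 (SD, n = 3). The ubiquitin ligase MDM2 was at 0.30 (SE 0.27), SESN1 at 0.42 (SE 0.23), the antiproliferative factor BTG2 at 0.30 (SE 0.17), ATF3 at 0.33 (SE 0.24), the mitochondrial reductase FDXR at 0.13 (SE 0.15), and the cyclin CCNB1 at -0.35 (SE 0.24). The repair factors XPC and DDB2 were at 0.020 (SE 0.34) and 0.014 (SE 0.24), the phosphatase PPM1D at 0.006 (SE 0.22), and the immediate early factors FOS and EGR1 at 0.075 (SE 0.18) and -0.048 (SE 0.20). Leaving out 1 array gave 0.16 for MDM2 without unirradiated 16 h replicate 1, 0.26 for SESN1 without unirradiated 16 h replicate 2, 0.52 and 0.18 for ATF3 without irradiated 16 h replicates 2 and 3, and -0.10 for CCNB1 without irradiated 16 h replicate 3. It gave 0.195 for BTG2 without unirradiated 16 h replicate 1, 0.084 for FDXR without unirradiated 16 h replicate 3 and 0.009 for FOS without irradiated 16 h replicate 3. Over the fits without 1 array XPC ran from -0.075 to 0.086, DDB2 from -0.126 to 0.226, PPM1D from -0.181 to 0.196 and EGR1 from -0.090 to 0.018. Within slide 3 GDF15 differed by 0.03 and CDKN1A by 0.21. GADD45A was not tested, because its probe carried an outlier flag on 10 of the 12 arrays.

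**Figure D3:**
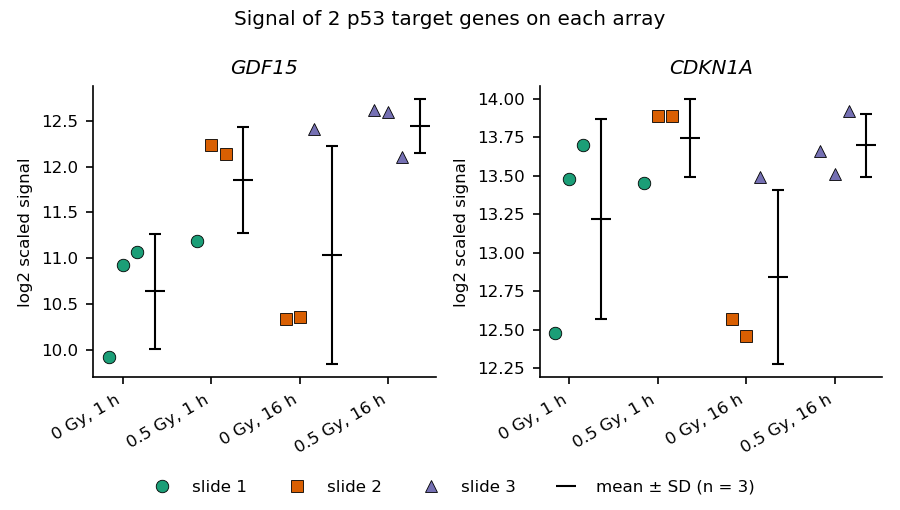
Log2 scaled signal of GDF15 and CDKN1A (y axes, which do not start at 0) on each array by group; points are arrays, marked by slide, and bars are means ± SD (n = 3). GDF15 was at 10.33 and 10.36 on unirradiated 16 h replicates 1 and 2 and at 12.41 on replicate 3, beside 12.1 to 12.62 on the irradiated arrays of the same slide.

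At 1 h, 4 lists passed the preset-correlation test, and adjusted p was 0.916 with an estimated correlation for each. Mitosis genes were lower, with a median of -0.36 and 20 of 27 members below 0, among them AURKA, a spindle kinase, at -1.97 (SE 0.42), the checkpoint kinase TTK at -1.10 (SE 0.24), securin PTTG1 at -0.95 (SE 0.27) and HMMR at -1.76 (SE 0.51). AURKA and TTK lay in rows 260 to 330 and columns 11 to 50, where uncalled genes had a median of -0.72 against 0.09 elsewhere. After local spatial centring the mitosis median was -0.34 (preset-correlation adjusted p = 0.0175). This area and the centring were chosen after seeing the data. Metallothioneins, which bind zinc and copper, were lower with a median of -0.31 and 9 of 10 members below 0, among them MT1G at -0.94 (SE 0.26), MT1H at -1.01 (SE 0.33) and MT1L at -0.98 (SE 0.35). Heat shock proteins were higher with a median of 0.29 and 15 of 19 members above 0, among them the chaperones HSPD1 at 0.76 (SE 0.31) and HSPA6 at 0.49 (SE 0.17) and the co-chaperone DNAJA1 at 1.25 (SE 0.29), the last over 1 unirradiated and 2 irradiated arrays. Cytosolic ribosomal proteins were higher with a median of 0.16 and 33 of 44 members above 0, with RPL23 at 0.41 (SE 0.16) and RPS14 at 0.60 (SE 0.26) but RPL34 at -1.03 (SE 0.40). Without unirradiated 1 h replicate 1 HSPD1 was at 0.32, without unirradiated 1 h replicate 2 RPL23 at 0.27, and without unirradiated 1 h replicate 3 RPS14 at 0.27. Without irradiated 1 h replicate 2 MT1H was at -0.54, MT1L at -0.56 and RPL34 at -1.55, and without irradiated 1 h replicate 1 RPL34 was at -0.53. At least 1 other probe gave the opposite sign for MT1G (0.061), RPL23 (-0.66), RPL34 (0.35) and RPS14 (-0.61). The 37 p53 targets had a median of 0.23 and did not pass, with adjusted p = 0.0671 and adjusted p = 0.916 with an estimated correlation. Their mean differed by 0.014 within slide 1, and a fixed slide block gave a median of -0.078 and a downward direction (adjusted p = 0.751). The p53 list passed the preset-correlation test without irradiated 1 h replicate 1 (0.38, adjusted p = 0.00972) or unirradiated 16 h replicate 3 (0.23, 0.0388). It also passed in 3 alternatives chosen after seeing the data, with flagged spots kept (0.25, 0.0406), over genes with no flag (0.25, 0.0291) and after local spatial centring (0.18, 0.0126).

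In the preset-correlation test the adjusted p was 0.022 for mitosis and for metallothioneins, 0.0446 for heat shock and 0.0454 for ribosomal proteins. The rotation test fry passed heat shock alone, at 0.042. Adjusted over the list alone, 4 mitosis genes and 1 metallothionein were lower, and 0 members of the 4 lists passed over all genes. Within slide 1 the means differed by -0.53 for mitosis, -0.10 for metallothioneins, 0.17 for heat shock and 0.14 for ribosomal proteins. A fixed slide block gave medians of -0.46, 0.011, 0.065 and 0.15, and the metallothionein and heat shock calls ended. At 1 h that fit compared the groups on slide 1 alone and rested on 1 irradiated array. That fit called DNA replication lower, at -0.40 (adjusted p = 0.0204), which did not pass as reported, at -0.15 (adjusted p = 0.659, and adjusted p = 0.916 with an estimated correlation). Under normexp, which moved the median of all genes from 0.053 to 0.137, the mitosis median was 0.16, the heat shock median 0.28 and the ribosomal median 0.17, and these 3 calls ended. Without unirradiated 1 h replicate 1, whose replication and mitosis scores of 0.711 and 0.612 stood above the -0.668 to -0.664 and -0.445 to -0.319 of its group, no list passed and the mitosis median was -0.072. The count of lists was 1 without unirradiated 1 h replicate 2, and 2 without unirradiated 1 h replicate 3 or irradiated 1 h replicates 2 or 3. Without irradiated 1 h replicate 1, 3 lists passed and the mitosis median was -0.29, no longer past the threshold, while heat shock was at 0.45 and metallothioneins at -0.50. The metallothionein call was lost without any unirradiated 1 h array (-0.41, -0.34 and -0.34) or irradiated 1 h replicate 3 (-0.23). The heat shock call was lost without any unirradiated 1 h array (0.31, 0.29 and 0.23) or irradiated 1 h replicates 2 (0.20) or 3 (0.23). The ribosomal call was lost without unirradiated 1 h replicates 1 (0.055) or 2 (0.17), irradiated 1 h replicates 1 (0.17) or 2 (0.13), unirradiated 16 h replicate 2 or any irradiated 16 h array (0.16 each).

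Single genes at 1 h numbered 49 of 22037, 3 higher and 46 lower. Among the named ones, RTRAF, an RNA transcription and transport factor, rose by 1.15 on the log2 scale (SE 0.18, adjusted p = 0.0486). All 3 higher genes lay in the 80 outer rows at the top or at the bottom of the array, an area chosen after seeing the data. Those rows held 29.2% of tested genes and 29 of the 30 higher probes with an unadjusted p under 0.001. With flagged spots kept, RTRAF was at 0.77 (limma adjusted p = 0.211). CGAS, the cytosolic DNA sensor, fell by 3.66 (SE 0.25, adjusted p = 7.41e-04), the dynactin subunit DCTN1 fell by 3.23 (SE 0.24, adjusted p = 7.41e-04), and LOC100128364 fell by 2.81 (SE 0.22, adjusted p = 7.41e-04). The hormone gene OXT fell by 3.02 (SE 0.28, adjusted p = 3.25e-03), the trace amine receptor TAAR5 fell by 4.94 (SE 0.41, adjusted p = 4.75e-03) and the dynein DNAH2 fell by 3.50 (SE 0.32, adjusted p = 9.19e-03). ACBD4, ATXN1L, the chemokine CXCL3 and LOC653884 also fell, with log2 changes of -3.52, -2.25, -2.93 and -3.72 and adjusted p between 9.27e-03 and 0.0484. Of genes that did not pass, EIF3H was at 1.61 over 1 unirradiated and 2 irradiated arrays, and HYKK was an estimated 3.01-fold higher from below background (adjusted p = 0.0837). The chemokine CCL20 at 1.29 (SE 0.27, adjusted p = 0.115) and RNF139 at 1.10 (SE 0.23, adjusted p = 0.115) did not pass either. HYKK, CCL20 and RNF139 lay in the outer rows too. In the panel GDF15 was at 1.21 (SE 0.53, adjusted p = 0.266), CDKN1A at 0.52 (SE 0.34), XPC at 0.70 (SE 0.34), MDM2 at 0.31 (SE 0.27), FDXR at 0.28 (SE 0.15), EGR1 at 0.34 (SE 0.20), ATF3 at 0.32 (SE 0.24), FOS at 0.21 (SE 0.18), PPM1D at 0.12 (SE 0.22), DDB2 at 0.065 (SE 0.24), CCNB1 at 0.027 (SE 0.24), SESN1 at -0.008 (SE 0.23) and BTG2 at -0.022 (SE 0.17), and 0 of the 13 passed. Without unirradiated 1 h replicate 1 CDKN1A was at 0.15, MDM2 at -0.049, FDXR at 0.18, XPC at 1.15, EGR1 at 0.57 and FOS at 0.40, and without unirradiated 1 h replicate 2 XPC was at 0.31 and FOS at 0.060. Without unirradiated 1 h replicate 3 EGR1 was at 0.20, and ATF3 was at 0.52 and 0.15 without irradiated 1 h replicates 1 and 3. Over the fits without 1 array PPM1D ran from 0.020 to 0.283, DDB2 from -0.090 to 0.247, CCNB1 from -0.124 to 0.203, SESN1 from -0.225 to 0.140 and BTG2 from -0.167 to 0.086.

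In 27 of the 49 called genes, all 27 lower, the spot of irradiated 1 h replicate 1, the 1 irradiated array on slide 1, carried an outlier flag and was left out. For these 27 the test set irradiated arrays of slide 2 against unirradiated arrays of slide 1, so irradiation and slide cannot be told apart. With that spot kept, irradiated 1 h replicate 1 lay a median of 0.32 above the unirradiated 1 h mean, while irradiated 1 h replicates 2 and 3 on slide 2 lay at -3.24 and the 16 h arrays at -3.46. The other 22 called genes, 19 lower and 3 higher, had a value on that array. It lay below the unirradiated 1 h mean in all 19 lower ones, at a median of -1.15 and between -2.54 and -0.81, against -1.64 on irradiated 1 h replicates 2 and 3. Of these 19, 15 lay in rows 260 to 330 and columns 11 to 50, an area chosen after seeing the data that held 1406 of the 22037 tested genes, where uncalled genes had a median of -0.72 at 1 h against 0.09 elsewhere. After local spatial centring, an alternative chosen after seeing the data, 0 of the 19 and 19 of the 27 stayed called, with LOC653884 at -3.65 (adjusted p = 0.121). TAAR5 and DNAH2 rested on 1 unirradiated and 2 irradiated arrays. With all flagged spots kept, an alternative chosen after seeing the data, 3 genes were called in place of 49, 0 of the 27 and 3 of the 22, and the median log2 change of the 19 was -1.48 with or without those spots. The 27 then had log2 changes between -3.57 and -0.82. At an unadjusted p under 0.05, 3998 genes were counted, 2162 of them higher, against 1102 expected. DNAH2 turned to 0.45 under normexp and to 0.23 after local spatial centring. Other probes of DNAH2 and CXCL3 gave 0.42 and 0.47, and that of ACBD4 -0.002. Within slide 1 the changes were 0.94 for RTRAF and -2.11 for LOC653884, and the other called genes given above had no value there. The fit with slide as a fixed block compared the 1 h groups on slide 1 alone, with 1 irradiated array. Fitting slide as a fixed block called 108 genes, 2 of them among the 49, with RTRAF at 0.94 and no longer past the threshold and LOC653884 at -2.11. The count was 0 under normexp and from the arrays of the contrast alone, 3 over genes with no flag, 30 without a filter on dim probes, 26 after local spatial centring and 2662 with array weights. With the replicate number as a block it was 8.

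Leaving out 1 array moved the 1 h count between 13 and 1729. It was 1729 without irradiated 1 h replicate 1, 723 without unirradiated 1 h replicate 1, 26 without unirradiated 1 h replicate 2, 21 without irradiated 1 h replicate 2 and 13 without irradiated 1 h replicate 3. Without a 16 h array it was 22, 20 and 22 for the unirradiated replicates 1 to 3 and 22 and 21 for irradiated replicates 1 and 2. The call of RTRAF was lost in 10 of these 12 fits, those of LOC653884 and CXCL3 in 9 each, and those of ACBD4 and ATXN1L in 2 each, without irradiated 1 h replicates 2 or 3. The calls of CGAS, DCTN1, OXT and LOC100128364 held in all 12 fits, and those of TAAR5 and DNAH2 in 11, where the fit without their 1 unirradiated 1 h array, on which these calls rest, could not be made. For these genes the flagged spot of irradiated 1 h replicate 1 entered none of the fits, so they do not test that array. With flagged spots kept, the limma adjusted p was 0.185 for CGAS, 0.264 for DCTN1, 0.231 for OXT and 0.196 for LOC100128364.

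**Figure D4:**
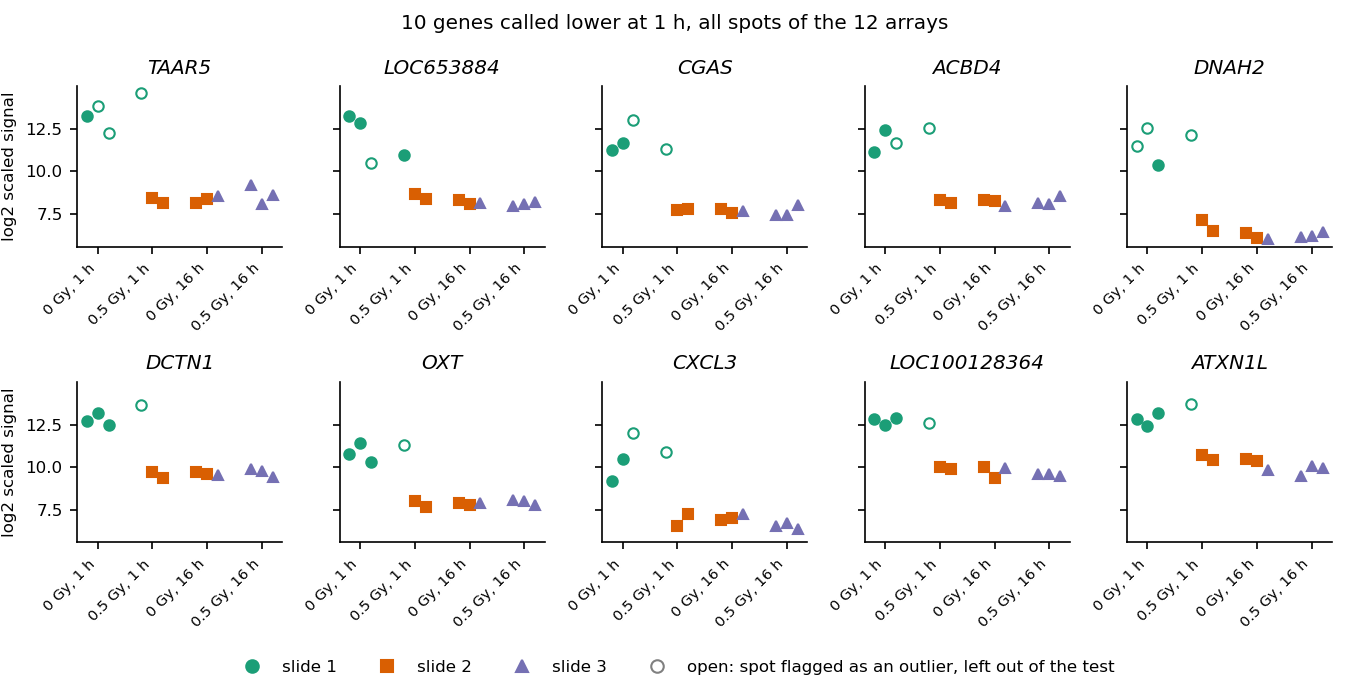
Log2 scaled signal (y axis, which does not start at 0) of 10 genes called lower at 1 h, on each of the 12 arrays by group; symbols give the slide, and open symbols are spots flagged as outliers, which the test left out. The irradiated 1 h array on slide 1 lay with the unirradiated arrays of its slide for most of these genes, and across the 27 called genes flagged on it a median of 0.32 above their mean.

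Averaged over both times, 7 lists passed the preset-correlation test, and 0 did in fry or with an estimated correlation, where the lowest was adjusted p = 0.483 with an estimated correlation. The p53 targets were higher with a median of 0.21 and 33 of 37 members above 0, cytosolic ribosomal proteins at 0.10, heat shock proteins at 0.18 and cholesterol synthesis genes at 0.13. Mitosis genes were lower at -0.43, DNA replication at -0.40 and metallothioneins at -0.38. Adjusted p was 1.2e-05 for mitosis, 2.36e-05 for p53 targets, 1.73e-03 for metallothioneins and ribosomal proteins, 2.46e-03 for replication and heat shock, and 0.0185 for cholesterol synthesis. With an estimated correlation the adjusted p was 0.483 for p53, metallothioneins, heat shock and cholesterol, 0.515 for mitosis and ribosomal proteins, and 0.67 for replication. Adjusted over the list alone, 2 p53 targets were higher, 4 mitosis genes and 1 metallothionein were lower, and 0 passed over all genes. Under a fixed slide block the medians were 0.014 for p53, -0.25 for replication, -0.039 for metallothioneins and -0.016 for cholesterol, whose calls ended, and -0.32 for mitosis, 0.12 for heat shock and 0.19 for ribosomal proteins, whose calls held. That fit also called replication-dependent histones higher (0.18, adjusted p = 0.0323) and endothelial markers lower (-0.29, adjusted p = 0.0184). Neither passed as reported: histones had 0.091 (adjusted p = 0.0583, and adjusted p = 0.483 with an estimated correlation) and endothelial markers -0.096 (adjusted p = 0.24, and adjusted p = 0.515 with an estimated correlation). Under normexp the ribosomal list stood at 0.018 and cholesterol synthesis at 0.008 against a median of 0.129 for all genes, each opposite to its first direction relative to that median, and mitosis at -0.022 and heat shock at 0.13 no longer passed. Replication lost its call without unirradiated 1 h replicate 1 (-0.22) or irradiated 1 h replicate 1 (-0.33), and cholesterol synthesis without unirradiated 1 h replicate 2 (0.13) or irradiated 1 h replicate 3 (0.11). Without unirradiated 1 h replicate 1 mitosis passed at -0.29 and ribosomal proteins at 0.063, without unirradiated 16 h replicate 3 ribosomal proteins at 0.065, and without unirradiated 16 h replicate 1 metallothioneins at -0.23.

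The averaged effect called 19 single genes, 0 higher and 19 lower. CGAS fell by 1.84 (SE 0.16, adjusted p = 7.5e-03), LOC100128364 fell by 1.51 (SE 0.15, adjusted p = 7.5e-03), DCTN1 fell by 1.59 (SE 0.16, adjusted p = 7.81e-03), TAAR5 fell by 2.34 (SE 0.24, adjusted p = 0.026) and DNAH2 fell by 1.71 (SE 0.19, adjusted p = 0.0337), both with 1 array in the unirradiated 1 h group. Higher but not past the threshold were CCL20 at 0.93 (SE 0.19, adjusted p = 0.181), the melanin synthesis enzyme TYRP1 at 1.01 (SE 0.23, adjusted p = 0.27), and HYKK, which has no exact change because it was not well above background in unirradiated tissue at either time (adjusted p = 0.18). Of the 19 genes, 12 had the flagged spot on irradiated 1 h replicate 1, and 0 genes were called with flagged spots kept. For those 12 irradiation and slide cannot be told apart in the 1 h part of the average. A fixed slide block called 50 genes, a replicate block 1, normexp 0, genes with no flag 0, local spatial centring 40 and array weights 1374. The count was 788 without irradiated 1 h replicate 1, 170 without unirradiated 1 h replicate 1, 7 without irradiated 1 h replicate 2 and 1 without irradiated 1 h replicate 3. Without a 16 h array it was 9, 7 and 10 for unirradiated replicates 1 to 3 and 9, 11 and 8 for irradiated replicates 1 to 3. The calls of CGAS, DCTN1 and LOC100128364 were lost in 1 of 12 fits, without irradiated 1 h replicate 3, that of TAAR5 in 6 of 11 and that of DNAH2 in 7 of 11, the fit without their lone unirradiated 1 h array not being possible.

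In the test of the difference itself, 11 genes were called. The gap between irradiated and unirradiated arrays was higher at 16 h than at 1 h for 9 of them and lower for 2. The 9 were led by the genes called lower at 1 h: TAAR5 at 5.21 (SE 0.49, adjusted p = 0.0193), CGAS at 3.64 (SE 0.32, adjusted p = 9.79e-03), DNAH2 at 3.59 (SE 0.38, adjusted p = 0.0335), DCTN1 at 3.28 (SE 0.33, adjusted p = 9.79e-03) and OXT at 3.11 (SE 0.38, adjusted p = 0.0265), with LOC100128364 at 2.61. TAAR5 and DNAH2 had a value on 1 unirradiated 1 h array, and on 2 irradiated ones, so their differences rest on few arrays. CPN1 at -1.87 (SE 0.30), KRTAP4-11 at -1.60 (SE 0.26) and ENPP4 at -1.96 (SE 0.36) did not pass, nor did LOC401176, which has no exact difference because it was below background after irradiation at 16 h, with adjusted p between 0.102 and 0.185 for the 4. Of the 11 genes, 9 had the flagged spot on irradiated 1 h replicate 1, and 0 genes were called with flagged spots kept. For those 9 the 1 h values left were irradiated on slide 2 and unirradiated on slide 1. Irradiation and slide therefore cannot be told apart in their 1 h part. No gene list differed between the times in camera, where 2 lists had an unadjusted p under 0.05, and 0 lists passed with an estimated correlation or in fry. The p53 targets had a median difference of -0.015 and a mean of -0.004, against an upward direction in camera, and the DNA replication list -0.59 with adjusted p = 0.339. A fixed slide block called 34 genes and 0 lists, normexp called 0 genes and 5 lists, and a replicate block called 1 gene. The gene count was 5 without a filter on dim probes, 0 over genes with no flag, 28 after local spatial centring and 2068 with array weights. The gene count was 528 without irradiated 1 h replicate 1, 274 without unirradiated 1 h replicate 1 and 1 without irradiated 1 h replicate 3. It was 4, 5 and 6 without unirradiated 16 h replicates 1 to 3, and 5, 7 and 5 without irradiated 16 h replicates 1 to 3. Without unirradiated 1 h replicate 1, unirradiated 16 h replicate 3 or irradiated 16 h replicate 3, 1 list passed. The calls of CGAS and DCTN1 were lost without irradiated 1 h replicate 3 alone (3.69 and 3.08), that of LOC100128364 in 6 of 12 fits without 1 array, that of OXT in 8 of 12, that of TAAR5 in 6 of 11 and that of DNAH2 in 7 of 11, again without a fit that leaves out their lone unirradiated 1 h array.

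Between 1 h and 16 h in unirradiated tissues, 5 lists passed the preset-correlation test, and for each adjusted p was 0.549 with an estimated correlation. All 31 measured DNA replication genes lay above 0, with a median of 0.73, among them UHRF1 at 1.57 (SE 0.46), RFC4 at 1.49 (SE 0.48), TYMS, which makes thymidylate, at 1.47 (SE 0.51) and the licensing inhibitor GMNN at 0.81 (SE 0.21). Of 27 mitosis genes 26 lay above 0, with a median of 0.53, among them CCNB1 at 0.81 (SE 0.24), CCNB2 at 1.16 (SE 0.39), KIF11 at 0.53 (SE 0.18) and CENPE at 0.81 (SE 0.26). Double-strand break repair genes had a median of 0.43, with CHEK2 at 1.19 (SE 0.25) and RBBP8 at 0.68 (SE 0.25). Epidermal barrier lipid genes had a median of 0.23, where the ceramide synthase CERS3 rose by 0.97 (SE 0.17, adjusted p = 0.035), with SMPD1 at 0.61 (SE 0.23) and ELOVL4 at 0.56 (SE 0.22), or 0.29 without unirradiated 1 h replicate 3. Metallothioneins were lower with a median of -0.44, MT1A at -0.75 (SE 0.23) and MT1G at -0.73 (SE 0.26), while the zinc exporter SLC30A1 of the same list was at 0.50 (SE 0.19).

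The adjusted p of these lists was 1.9e-05 for replication, 7.32e-04 for mitosis, 2.31e-03 for repair, 0.0248 for barrier lipids and 0.0337 for metallothioneins, and 0 lists passed fry. Adjusted over the list alone, 1 repair gene and 1 barrier lipid gene were higher, and over all genes 1, CERS3. No slide held both unirradiated groups, so no value within a slide exists. The fit with slide as a fixed block thus linked the times through the irradiated 1 h arrays, of which 1 lay on slide 1. Its values are not a comparison of unirradiated arrays alone. Under a fixed slide block the medians were 0.71 for replication, 0.81 for mitosis, 0.48 for repair, 0.20 for barrier lipids and 0.26 for metallothioneins, and the last 3 calls ended, the last with its sign turned. That fit called the p53 targets lower at the later time, at -0.37 (adjusted p = 1.21e-05), where they did not pass as reported and had the opposite sign (0.26, adjusted p = 0.287, and adjusted p = 0.761 with an estimated correlation). Under normexp, which moved the median of all genes from 0.058 to -0.374, mitosis stood at -0.12, repair at -0.14 and metallothioneins at -0.49, and those calls ended, while replication at 0.47 and barrier lipids at 0.64 kept theirs. The count of lists was 3 without unirradiated 1 h replicates 2 or 3 or unirradiated 16 h replicate 3. Leaving out unirradiated 1 h replicate 1 gave 1.16 for replication and 0.37 for barrier lipids, leaving out unirradiated 16 h replicate 1 gave -0.72 for metallothioneins, and leaving out unirradiated 16 h replicate 3 gave 0.74 for mitosis and 0.62 for repair. The barrier lipid call was lost without unirradiated 1 h replicates 2 (0.21) or 3 (0.19) or unirradiated 16 h replicate 3 (0.28). The metallothionein call was lost without any unirradiated 1 h array (-0.59, -0.45 and -0.38), unirradiated 16 h replicate 3 (-0.18) or irradiated 16 h replicate 3 (-0.44).

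Between unirradiated tissues at 1 h and 16 h, 155 single genes were called, 17 higher and 138 lower at 16 h. All unirradiated 1 h arrays lay on slide 1 and no 16 h array did, so time and slide cannot be told apart. The adhesion molecule EPCAM rose by 1.43 (SE 0.27, adjusted p = 0.0426), the protease inhibitor SPINT1 by 1.35 (SE 0.23, adjusted p = 0.0343), the gluconeogenic enzyme FBP1 by 1.28 (SE 0.23, adjusted p = 0.0359), MMS22L by 2.01 (SE 0.33, adjusted p = 0.0326), and RNF139, DOCK11 and RTRAF by 1.22, 1.19 and 1.17. EPHB1 and HSD17B11 were not well above background at 1 h and were an estimated 2.6-fold and 2.35-fold higher at 16 h. These folds depend on the background step, and under normexp both genes were lower at 16 h (-0.78 and -0.902). RAPGEF3 fell by 5.13 (SE 0.94, adjusted p = 0.0426), TAAR5 fell by 4.86 (SE 0.38, adjusted p = 2.76e-03) from a value on 1 unirradiated 1 h array, LOC653884 fell by 4.84 (SE 0.60, adjusted p = 0.0125), and CGAS fell by 3.78 (SE 0.23, adjusted p = 2.19e-04). ELF5, RARA, ZNF548 and CYB561D1 also fell, with log2 changes of -4.11, -4.05, -3.82 and -3.81 and adjusted p between 0.0416 and 0.0466. Other probes of ELF5 gave 0.22 and 0.23, that of RARA 0.24, that of RAPGEF3 -0.012 and that of ZNF548 -0.053.

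Over the 138 genes lower at 16 h, irradiated 1 h replicate 1 on slide 1 lay a median of -0.47 from the unirradiated 1 h mean, against -2.11 for irradiated 1 h replicates 2 and 3 on slide 2, -2.26 for unirradiated and -2.43 for irradiated 16 h arrays. In 100 of the 138 that array was nearer to the unirradiated 1 h arrays of its slide than to the irradiated 1 h arrays of slide 2. Arrays of slide 2 harvested at 1 h thus lay near the 16 h arrays, and the falls cannot be put down to time rather than slide. Of the 17 higher genes, 6 lay in rows 40 to 55 of the first 12 columns, which held 93 tested genes, an area chosen after seeing the data. At 1 h and over time, 33 genes were called lower in both. The comparisons share the unirradiated 1 h arrays, and 100 simulations without effects gave a mean overlap of 12.67 and at most 19 in lists of the same sizes, while independent lists would share 0.288. With 3 shared arrays no split of them leaves 2 in each part, so the share of the overlap due to them was not tested on the real arrays. The 33 exceeded all simulations, but these held no effect of slide, and slide 1 against other slides enters both comparisons. A fixed slide block, which linked the times through the irradiated 1 h arrays, called 44 genes over time. Normexp called 3, the fit without a filter on dim probes 46, genes with no flag 0 and a replicate block 43. Larger counts came from a variance trend with robust settings (248), local spatial centring (370), the arrays of the contrast alone (583) and array weights (7474). The count was 2025 without unirradiated 1 h replicate 1, 1143 and 249 without irradiated 1 h replicates 1 and 2, and 26 and 70 without unirradiated 1 h replicates 2 and 3. It was 30, 15 and 14 without unirradiated 16 h replicates 1 to 3 and 45, 41 and 58 without irradiated 16 h replicates 1 to 3. Of the genes named, CGAS kept its call in all 12 fits and TAAR5 in 11, where the fit without its lone unirradiated 1 h array could not be made. LOC653884 lost its call in 3 of 12, SPINT1 in 6, MMS22L, EPCAM, EPHB1, FBP1, RTRAF and ZNF548 in 7 each, and HSD17B11, RNF139, DOCK11, RAPGEF3, ELF5, RARA, CYB561D1 and CERS3 in 8 each.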

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

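The tests chosen only after the result was seen were the first columns of spots at 16 h, local spatial centring of the 16 h and 1 h calls, the area and the neighbouring spots of the 1 h calls, the test of an irradiation effect on the list score and that of slide 3 against slide 2, the counts with outlier-flagged spots kept, the test of pyrimidine-rich probes by whether that flag was set, the test of named transcripts at 1 h by the same flag, and the margin by which other probes of the same genes were judged.

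The gap between irradiated and unirradiated arrays differed between 16 h and 1 h, in the test of the difference itself, for 11 genes. The differences on the log2 scale were 5.21 for TAAR5, 3.64 for CGAS, 3.59 for DNAH2, 3.28 for DCTN1, 3.11 for OXT and 2.61 for LOC100128364. Of 100 drawn splits of the arrays within each time, 21 gave as many genes and the highest other count was 201, so chance cannot be excluded. The splits were drawn without regard to slide, so their counts mix slide differences with chance. For gene lists the count was 0, which all 100 splits reached, with 10 as the highest other.

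At 1 h, 27 of the 49 called genes, and 9 of the 11 above, had the irradiated array of slide 1 left out for its outlier flag, and with such spots kept 0 of the 27 stayed called and that array lay a median of 0.32 above the unirradiated mean of its slide. The 27 then still had log2 changes between -3.57 and -0.82. With that array left out, irradiation and slide cannot be told apart for the 27. Uneven signal in an area of the array is argued against for the 27, whose uncalled neighbours had a median of -0.125 and of which 19 stayed called after local spatial centring, while a median of 61.67% C and T bases in their probes (51.67% in tested probes, 53.33% in tested probes with that flag, one-sided permutation p = 1e-05 against tested probes, the smallest the permutations can give) leaves bright pyrimidine-rich spots on slide 1 as a candidate explanation. For the 19 lower genes with a value on that array, 15 of them in 1 area with 6.4% of tested genes, uneven signal there may account for much of the change: uncalled neighbours had a median of -0.909, and centring brought the median from -1.48 (median SE 0.23) to -0.82 (0.22) and ended all 19 calls (adjusted p of 0.0917 to 0.646). For 2 of the 19, LOC653884 among them, neighbours lay above 0, and bright spots stay open for the 19, with 55% C and T bases (permutation p = 0.0905). A change of the named transcripts is argued against for ACBD4, CXCL3 and DNAH2 of the 27, whose other probes had a median of 0.425 (-0.002 to 0.475) where -3.502 was reported, and stays open for the 24 with no other probe and for the 19, where 3 other probes of 2 genes had a median of -0.126 (-1.047 to 0.364).

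The calls at 16 h lay at the left edge of the arrays: 8 of 8 were in the first 12 columns, chosen for these calls, against 2929 of 22037 tested genes. Local spatial centring brought the other genes of these columns from a median of -0.105 to -0.007, and 8 of 8 stayed called, at a median of -1.92 (median SE 0.19) from -2.18 (0.26). But of the 71 calls gained by it 29 lay in these columns (Fisher p = 7.33e-09), so a pattern by position remained. It was fitted on spots well above background, and may miss uneven signal of dim ones. The centring thus cannot decide whether uneven signal was the cause. Position at the edge, smooth or not, stays open, since the columns were drawn from these calls. A change of the named transcripts stays open, because 4 other probes of 3 genes were too few, with a median of -0.259 and a range from -0.606 to 0.481 where the reported probes had -1.199.

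A score of p53 minus replication at 16 h, which leaves out mitosis, differed by 0.929 between the groups, by 1.34 without unirradiated 16 h replicate 3, and by 0.105 within slide 3, where mitosis differed by -0.189 against -0.555 over all 16 h arrays. Position at the left edge is argued against for the preset-correlation calls of all 3 lists. The test was a mild one, above all for mitosis. Of the measured members, 7 of 37 p53, 8 of 31 replication and 3 of 27 mitosis genes lay in the first 12 columns. Without those columns 3 of 3 stayed past the threshold of that test (adjusted p of 2.78e-09, 2.78e-09 and 6.42e-09). With an estimated correlation, over all columns, none of the 3 passed (adjusted p = 0.279 for p53 and 0.473 for replication and mitosis). A shift between slides 3 and 2 stays open: the unirradiated 16 h array of slide 3 lay 1.237 above those of slide 2, but it was 1 array, all irradiated 16 h arrays were on slide 3, and slide 2 was not low as a whole, with irradiated 1 h replicates 2 and 3 at 0.434 and 0.415. An effect of irradiation stays open too: 0.105 within slide 3 is small, and 0.383 within slide 1 rests on unirradiated 1 h replicate 1 at -0.87. A check that 1 unirradiated 16 h array lay at the level of the irradiated ones was run and dropped as an explanation after its result was seen, with that array at 0.173 beside irradiated arrays at 0.188 to 0.433.

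At 1 h, 3 of the 10 splits of the 6 arrays gave at least 49 genes and the highest other gave 312, with irradiated 1 h replicate 1 beside unirradiated replicates 2 and 3. Such a count points to a structure of the samples, and that split follows slide 1 apart from unirradiated replicate 1. At 1 h a fixed slide block compares the groups on slide 1 alone, with 1 irradiated array. The fit with slide as a fixed block called 108 genes. For lists at 1 h, 2 splits reached 4 and the highest other gave 8. At 16 h, 1 split, the real one, reached 8 genes, with 0 as the highest other, and 1 reached 11 lists, with 8. For time, 1 split reached 155 genes, with 27 as the highest other, and 3 reached 5 lists, with 7. With 10 splits each, these are too few for a share under 0.05. For the average, 11 of 100 splits reached 19 genes, with 174 as the highest other, and 5 reached 7 lists, with 10, so chance cannot be excluded. These splits disregarded slide as well, so slide differences enter their counts beside chance.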

How the results depend on the processing

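The tests chosen only after the result was seen were those that kept spots with an outlier flag, left out genes with any such flag, left out the first 12 columns of spots, or used local spatial centring. Over all alternatives and the fits without 1 array, the 27 list results kept direction and side of the threshold in 463 cases, lost the call in 148 and turned in 10. The named genes did so in 3394 cases, lost a call in 433, gained one in 116 and turned in 91, and counts stayed within 1.5 times in 147, were lower in 91 and higher in 42. The deposited value table equals the processed signal, so it could not differ and is not counted. Median centring, the filter over all 12 arrays, the mean of probes, single probes, slide as a random block (correlation -0.006) and a minimum fold of 1.5 kept every count within 1.5 times. The cause of the changes below was not tested, and in some alternatives fewer genes or arrays entered. Signal over background limits the dim genes: probes near background depend on the floor and on the background step, and TAAR5, DNAH2, EIF3H and DNAJA1 at 1 h rest on a lone unirradiated array assumed to vary like the others, as do their values for the average, the difference and time.

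With normexp the gene counts were 0 at 1 h (49 as reported), 0 at 16 h (8), 0 for the average (19), 0 for the difference (11) and 3 for time (155), and the list counts 1 at 1 h (4), 5 for the difference (0) and 17 for time (5). It turned lists at 16 h (histones 0.010, immediate early genes -0.060, early differentiation -0.065, heat shock -0.090, ribosomal -0.148) and in the average (cholesterol 0.008, ribosomal 0.018). It turned DNAH2 (0.445) and TTK (0.021) at 1 h, DNAH2 in the average (0.453), and at 16 h RRM2 (0.038), TOP2A (0.072), MRE11 (0.231), STAT2 (0.002), DNAJA1 (-0.072), RPS19 (-0.061), FDXR (-0.136) and DDB2 (-0.077). For time it turned MMS22L (-0.401), EPHB1 (-0.780), HSD17B11 (-0.902), DOCK11 (-0.089), CHEK2 (-0.318) and KIF11 (-0.261).

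Quantile normalization gave 7 lists at 16 h (11), 1 for the difference and 8 for time, and turned BTG2 (0.011) and SESN1 (0.023) at 1 h and PPM1D (-0.003) at 16 h. Median centring turned EGR1 at 16 h (0.002) and the mean of probes SESN1 at 1 h (0.372). Without a filter on dim probes the gene counts were 30 at 1 h, 1 at 16 h, 5 for the difference and 46 for time.

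Slide as a fixed block gave 108 genes at 1 h, 0 at 16 h, 50 for the average, 34 for the difference and 44 for time, with 3 lists at 16 h and 3 for time. Within each time its contrast came from 1 slide alone, with 1 irradiated array at 1 h and 1 unirradiated array at 16 h. The slide block turned the repair list (-0.051) and metallothioneins (0.038) at 16 h and metallothioneins over time (0.264). It turned DDB2 (-0.268), PPM1D (-0.011), ATF3 (-0.088) and CCNB1 (-0.032) at 1 h, CDT1 (0.022), H4C8 (-0.054), DSC2 (-0.069), MT2A (0.092), XPC (-0.112), PPM1D (-0.218) and FOS (-0.017) at 16 h, and CENPE (-0.063), MT1A (0.107) and MT1G (0.295) over time.

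The replicate numbers were not taken as a pairing, since the labels name 3 independent experiments but do not tie a number to 1 of them. Of 12 same-numbered pairs 1 correlated above 0.1 (-0.26 to 0.14), and 3 had their best partner under the same number. Slides cut across the replicate numbers, so this check cannot exclude that a number marked 1 experiment. A replicate block gave 8 genes at 1 h, 0 at 16 h, 1 for the average, 1 for the difference and 43 for time. The replicate block with slide gave 0 genes at 16 h, 0 for the average, 0 for the difference and 0 for time. It turned DDB2 (-0.477), PPM1D (-0.182), ATF3 (-0.010), EGR1 (-0.070) and CCNB1 (-0.320) at 1 h. At 16 h that block turned MRE11 (0.053), H4C8 (-0.051), MT1G (0.087), MT2A (0.072), SESN1 (-0.208), XPC (-0.149), DDB2 (-0.270), PPM1D (-0.478) and FOS (-0.041). Over time it turned KIF11 (-0.095), GMNN (-0.050), TYMS (-0.588), SMPD1 (-0.219), ELOVL4 (-0.160), MT1A (0.145), MT1G (0.388) and SLC30A1 (-0.111).

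Fitting the arrays of the contrast alone gave 0 genes at 1 h, 52 at 16 h and 583 for time, and a variance trend with robust settings 248 for time. Array weights gave 2662, 634, 1374, 2068 and 7474 genes at 1 h, 16 h, for the average, the difference and time, and turned BTG2 at 1 h (0.048) and XPC at 16 h (-0.072). An adjusted p under 0.10 gave 85 genes at 1 h, 14 at 16 h and 890 for time, and an unadjusted p under 0.001 gave 146, 72, 88, 61 and 330. With an estimated correlation 0 lists passed at 1 h, at 16 h, for the average and for time, and with fry 1 at 1 h and 0 at 16 h, for the average and for time.

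With spots kept whatever their outlier flag, the gene counts were 3 at 1 h, 0 for the average and 0 for the difference, and RPL34 at 1 h (0.656) and RPL4 at 16 h (0.051) turned. Genes with no outlier flag on any array gave 3 at 1 h, 0 for the average, 0 for the difference and 0 for time. This left out 1274 of 22037 tested genes, among them 30 of the 49 called at 1 h and 47 of the 155 over time. Calls of genes without a flag were lost too, for a cause that was not tested. Without the first 12 columns the counts were 0 genes at 16 h, 2 lists at 1 h and 3 lists for time, and RARA over time, then read by another probe, was 0.245. Local spatial centring gave 26 genes at 1 h, 79 at 16 h, 40 for the average, 28 for the difference and 370 for time, and 3 lists for the difference. It turned DNAH2 (0.234), BTG2 (0.236), SESN1 (0.643), DDB2 (-0.015) and CCNB1 (-0.363) at 1 h and DNAH2 in the average (0.077) and the difference (-0.315).

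Leaving out each array in turn gave 13 to 1729 genes at 1 h, 0 to 32 at 16 h, 1 to 788 for the average, 1 to 528 for the difference and 14 to 2025 for time. Lists ranged from 0 to 5 at 1 h, 7 to 12 at 16 h, 0 to 1 for the difference and 3 to 5 for time. At 1 h MDM2 ranged from -0.049 to 0.491, BTG2 from -0.167 to 0.086, SESN1 from -0.225 to 0.140, DDB2 from -0.090 to 0.247 and CCNB1 from -0.124 to 0.203. At 16 h MT2A ranged from -1.177 to 0.092, XPC from -0.075 to 0.086, DDB2 from -0.126 to 0.226, PPM1D from -0.181 to 0.196 and EGR1 from -0.090 to 0.018.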

Other observations

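The counts of probes by position at 1 h were chosen only after the result was seen, and the list results below were planned.

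The other gene lists give a picture of the tissue at 16 h after irradiation, and none of them passed camera. Basal keratinocyte genes, which mark the dividing layer, had a median log2 change of -0.11 (adjusted p = 0.771), genes of the cornified envelope -0.006 (0.12), barrier lipid genes 0.043 (0.0544) and wound keratinocyte genes 0.021 (0.259). Cholesterol synthesis stood at 0.065 (0.0544), matrix remodelling at -0.096 (0.196), NRF2 targets at -0.051 (0.971), the unfolded protein response at -0.030 (0.571) and hypoxia genes at -0.004 (0.259). Circadian clock genes were at -0.032 (0.471), apoptosis regulators at -0.018 (0.411), oxidative phosphorylation at -0.011 (0.196) and inflammatory cytokines at -0.007 (0.992). For the cornified envelope, hypoxia, circadian, apoptosis and oxidative phosphorylation lists the median lay below 0 and the mean above it (0.022, 0.032, 0.008, 0.007 and 0.028). For these and for the basal, NRF2, unfolded protein and melanocyte lists camera's direction was upward. Camera compares the test statistics of a list with those of the other genes. The medians of the basal and NRF2 lists lay below the median of -0.038 over all genes.

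Markers of other cell types did not pass the test at 16 h either. Melanocyte markers had a median of -0.021 (adjusted p = 0.992), fibroblast markers -0.060 (0.771), markers of Langerhans and other immune cells -0.16 (0.758) and endothelial markers -0.13 (0.224). Within slide 3 the means of these lists differed by -0.24, -0.30, -0.031 and -0.41.

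Position also marked the 1 h comparison. Of 30 probes higher at an unadjusted p under 0.001, 29 lay in the 80 outer rows at the top or at the bottom of the array, which held 6424 of 22037 tested genes (29.2%), and of 116 lower probes 6 lay there. Of the 116 lower probes 68 lay in rows 260 to 330 and columns 11 to 50, with 1406 tested genes (6.4%), and the 19 called lower genes with a value on the irradiated array of slide 1 lay closer together than random draws of tested genes (permutation p = 1e-04, the smallest 10000 draws can give).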
